A study of Oryza sativa with 11 samples.

How the data were processed

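RNA sequencing of whole rice anthers was analysed in 11 libraries from 4 groups: the wild type (WT) and the ostie1-1 mutant, each at anther stages 10 and 12. There were 3 libraries in each group except ostie1-1 at stage 12, which had 2. Groups and replicate numbers were taken from the sample labels, and a single table of expression values was used.

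The deposited values are FPKM (fragments per kilobase of transcript, relative to the fragments of the library), computed by the authors for each MSU rice transcript model. Per the submitters' processing notes, reads were aligned with HISAT2 2.2.0 to the IRGSP-1.0 genome and counted with featureCounts. How the counts became FPKM, which filters were applied and how reads shared between places were treated is not stated.

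FPKM were summed over the transcript models of a locus, which took 66338 models (185 of them on unplaced sequence) to 55986 loci. Of these, 16218 loci were listed at 0 in every library. The FPKM sums per library ranged from 749507 to 845797, and 17012 to 19162 loci per library reached an FPKM of 1. Read counts were not given. Below an FPKM of 0.3 the values of a locus in different libraries stood in ratios set by a step per library. With the step removed, 98.76% to 99.32% of the ratios to WT stage 10 replicate 1 were ratios of small whole numbers, within a log2 tolerance of 0.002. The steps gave depths of 0.914 to 1.17 relative to WT stage 10 replicate 1, so the libraries had similar depths, but the absolute depth is unknown and no counting interval was computed.

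Loci with several transcript models rarely reached the analysis. Of 6457 such loci 1256 (19.5%) were tested, against 20023 of 49529 loci with 1 model (40.4%). Among members of the gene lists the difference was wider, with 19 of 104 (18.3%) against 198 of 233 (85.0%), so a low value of a locus with several models is not read as absence of its transcript.

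Each library was divided by a median-of-ratios factor (0.726 to 1.32) and transformed as log2(FPKM + 1). Loci with an FPKM of at least 1 in at least 2 libraries were kept, which left 21279 genes. On this scale a fold change of a gene with a low FPKM is smaller than the ratio of its FPKM. A linear model with 1 mean per group was fitted to all 11 libraries with limma 3.58.1 (trended variance, R 4.3.3). It gave ostie1-1 against WT at each stage, stage 12 against stage 10 in each genotype, and the difference of the genotype effect between the stages. A gene passed at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Log2 fold changes are given with their standard error (SE) and FPKM with the standard deviation (SD). The labels number biological replicates without saying whether they come from separate plants, so the p-values measure the spread between these samples.

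Before the data were examined, 22 gene lists with 340 loci were fixed. They covered jasmonate (JA) biosynthesis and conjugation, JA signalling, JA-inducible defence, TCP transcription factors, tapetum regulators, pollen wall and anther cuticle, sugar supply to pollen, starch synthesis, late pollen, secondary wall cellulose and lignin, primary wall cellulose synthases, auxin synthesis and inactivation, gibberellin synthesis and signalling, aquaporins, photosynthesis (as a marker of green tissue), stamen identity MADS genes, pistil and glume MADS genes, meiosis, heat shock, the circadian clock, respiratory burst oxidases, and reference genes. The table held 337 of these loci and 217 were tested. For 17 lists with at least 5 tested members, camera compared the members with all other genes at a preset correlation of 0.01, with p adjusted over the lists. Each list was also run with an estimated correlation and with fry, which tests whether the genes of a set move on balance one way and does not compare them with other genes. Counts of members are also given adjusted over the list alone. Gene names were assigned to locus IDs from general knowledge. Neither the table nor the reference at hand pairs these IDs with names (0 LOC_Os entries in the reference), so each name is given with its ID and was not checked against an annotation. The ID of OsTIE1 could not be established this way and the gene is not used here.

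The genes named in the text follow a rule fixed at the same time. For each genotype comparison it took up to 2 genes with the largest rise and up to 2 with the largest fall among genes that passed, had groups that did not overlap and reached a mean FPKM of 5 in the higher group. It also took up to 5 members with the smallest adjusted p from each of the JA biosynthesis, JA signalling and TCP lists, and up to 3 from other lists where at least 2 members or the list test passed. For the stage comparison in WT it took up to 2 members from each list where at least 2 passed. Other genes are named as chosen after their values were seen.

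A stage index was computed per library as the mean log2 level of genes that rose from stage 10 to 12 minus that of genes that fell. Groups were compared on it with exact two-sided permutation tests, whose smallest possible p with these group sizes is 0.1. Because WT stage 10 replicate 3 stood apart from the other libraries of its group, counts and lists are also given without it.

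The alternatives tried were no scaling, rescaling to a common sum (TPM), quantile normalization, pseudocounts of 0.1 and 0.01 (the latter with robust variances), no filter on low values, an FPKM minimum of 5, fits with only the groups of a comparison, a replicate block, an absolute log2 fold change of at least 1, array weights, both other list tests, and leaving out each library in turn. Restricting the analysis to loci with 1 transcript model was added after seeing the data. The pipeline was tested on simulated data. Each real gene was drawn around its mean over all 11 libraries, with its residual spread the same in every library. At stage 10 the pipeline recovered 2 of 67 genes changed by a log2 value of 1, 31 of 67 changed by 2, and 48 of 66 changed by 3. Of 90 genes called there, 9 were unchanged. At stage 12 the pipeline recovered 0 of 67, 20 of 67 and 36 of 66, and of 59 genes called 3 were unchanged. A set of 12 changed genes was called by all list tests at both stages, and 0 of 50 unchanged sets were called by camera or by fry. No simulated library stood apart as WT stage 10 replicate 3 does, so recovery and false calls may differ in the real data. The simulated genes varied independently of each other. Lists that camera called between the genotypes in the real data had estimated correlations of 0.25 to 0.94. The simulation therefore does not show how often camera at the preset correlation calls an unchanged list of such genes. For single genes, simulated log2 changes of 1 and of 2 were mostly missed at these group sizes. Even changes of 3 were often missed at stage 12, with 36 of 66 recovered.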

Results

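Messenger RNA levels were measured in anthers of field-grown rice (Oryza sativa) to ask how OsTIE1, a transcriptional repressor that the series links to anther dehiscence, male sterility and the hormone JA, affects anther development. The ostie1-1 mutant was compared with WT at stage 10 (3 libraries each) and at stage 12 (2 and 3 libraries). In rice anther staging, microspores are vacuolated at stage 10 and pollen nears maturity at stage 12, shortly before the anther opens. The libraries had similar depths, as described above.

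WT stage 10 replicate 3 stood apart from the other libraries of its group. Its log2 levels correlated at 0.79 and 0.80 with WT stage 10 replicates 1 and 2, which correlated at 0.98 with each other, and at 0.88 to 0.90 with the ostie1-1 stage 10 libraries. Its 10 most abundant loci held 26.0% of the FPKM, against 9.63% and 10.7% in the other WT stage 10 libraries and 23.6% to 24.3% in ostie1-1 at stage 10. On the first principal component (44.6% of the variance) it lay at 108.0, beside ostie1-1 stage 10 (64.78 to 110.04) and far from WT stage 10 replicates 1 and 2 (-44.17 and -25.25). The library was kept as labelled. Counts and lists without it are given beside the main results it moves, and values of single genes only in some cases.

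**Figure D1:**
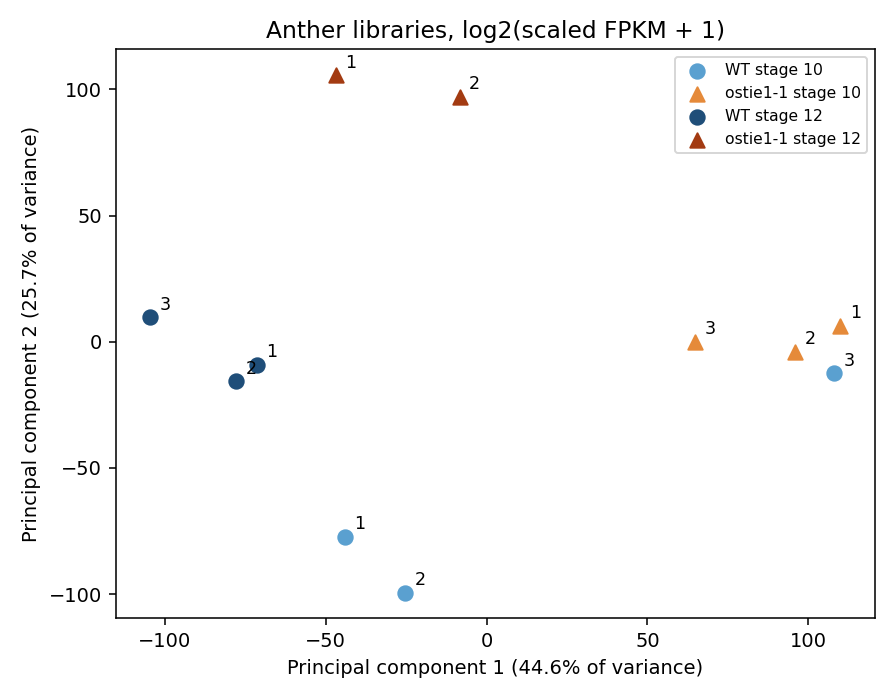
Position of the 11 anther libraries on the first and second principal components of log2(scaled FPKM + 1), with the percent of variance on each axis, the groups by colour and shape, and the replicate number beside each point. WT stage 10 replicate 3 lies at 108.0 on the first component, among the ostie1-1 stage 10 libraries (64.78 to 110.04).

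At stage 10, single genes of JA synthesis and JA signalling and a TCP gene rose in ostie1-1. The lipoxygenase gene LOC_Os04g37430, of the enzyme family that starts JA synthesis, rose from 3.08 ± 2.29 FPKM in WT to 21.7 ± 6.54 FPKM in ostie1-1 (SD, n = 3 each) with a log2 fold change of 2.69 (SE 0.54, adjusted p = 0.0261). It was higher in all 3 mutant libraries than in any WT library. JAZ8 (LOC_Os09g26780), a JAZ repressor that JA itself induces, rose from 12.0 ± 3.55 to 55.7 ± 19.1 FPKM (log2 fold change 2.23, SE 0.44, adjusted p = 0.0242), again with no overlap between the groups. A TCP transcription factor gene, LOC_Os11g07460, rose from 0.452 ± 0.494 to 5.12 ± 0.215 FPKM (log2 fold change 2.19, SE 0.39, adjusted p = 0.0132). TCP proteins are the known partners of TIE repressors.

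Of 14 tested JA signalling genes, 1 rose and 13 did not pass (2 adjusted over the list alone). Their median log2 fold change was 0.83, and camera placed the list above other genes (adjusted p = 0.00904). That call was lost at an adjusted p = 0.975 with an estimated correlation. JAZ11 (LOC_Os03g08320) had a log2 fold change of 1.88 (SE 0.48, adjusted p = 0.0673) and MYC2 (LOC_Os10g42430), the central JA-response activator, one of 1.32 (SE 0.44, adjusted p = 0.152). Of 11 JA biosynthesis genes, 1 rose and 10 did not pass (4 adjusted over the list alone). The median of that list was 0.39 (0.23 with unscaled FPKM, 0.21 with TPM) and camera gave an adjusted p = 0.105. AOS1 (LOC_Os03g55800), for allene oxide synthase, had a log2 fold change of 1.84 (SE 0.65, adjusted p = 0.173), and AOC (LOC_Os03g32314), for allene oxide cyclase, one of 1.32 (SE 0.44, adjusted p = 0.152). Of 10 JA-inducible defence genes, 0 passed with limma (2 at an unadjusted p below 0.05, 1 higher adjusted over the list alone, median 0.40, camera adjusted p = 0.522). Of 16 TCP genes, 1 rose and 15 did not pass (6 higher adjusted over the list alone), with a median of 0.69 and camera adjusted p = 0.00904 (adjusted p = 0.975 with an estimated correlation).

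WT stage 10 replicate 3 had the higher values of its group in these lists. It exceeded both other WT stage 10 libraries in 10 of 11 JA biosynthesis genes (median log2 difference 1.59), 10 of 14 JA signalling genes (1.44), 10 of 10 JA-inducible defence genes (2.53) and 14 of 16 TCP genes (0.93). AOS1 stood at 49.8 FPKM in it, at 10.8 and 10.2 in the other WT libraries, and at 83.0, 61.3 and 42.4 in ostie1-1. Without this library 6 of 11 JA biosynthesis genes, 8 of 14 JA signalling genes, 4 of 10 JA-inducible defence genes and 10 of 16 TCP genes passed, all higher in ostie1-1, and AOS1 had a log2 fold change of 2.77 (adjusted p = 6.6e-04). The camera adjusted p then was 0.00671 for JA biosynthesis, 0.00372 for JA signalling, 0.0245 for JA-inducible defence and 0.00372 for TCP genes, with 0.158 to 0.495 for these lists with an estimated correlation. Fry, which called no list at stage 10 with all libraries, then gave an adjusted p of 0.00274, 1.6e-04, 0.0168 and 0.00485 for them. The JA signalling call was lost without WT stage 10 replicate 2 (adjusted p = 0.0595) and the TCP call without ostie1-1 stage 10 replicate 1 (adjusted p = 0.156). With libraries other than WT stage 10 replicate 3 left out, camera was run at the preset correlation alone.

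Camera at the preset correlation also placed primary wall cellulose synthase genes, which build the walls of growing cells, higher in ostie1-1 at stage 10, and photosynthesis genes lower. CESA1 (LOC_Os05g08370) rose from 33.8 ± 1.82 to 76.2 ± 18.0 FPKM (n = 3 each, log2 fold change 1.28, SE 0.29, adjusted p = 0.0438), though it did not pass with unscaled FPKM or TPM. It was the 1 of 5 members that passed (2 adjusted over the list alone), CESA5 (LOC_Os03g62090) having a log2 fold change of 1.5 (SE 0.37, adjusted p = 0.0592). The list median was 1.28 and camera adjusted p was 0.00359 (adjusted p = 0.975 with an estimated correlation). WT stage 10 replicate 3 was above both other WT libraries in 5 of 5 members, and without it all 5 rose (camera adjusted p = 0.00583, adjusted p = 0.378 with an estimated correlation). Of 9 photosynthesis genes 0 passed with limma (4 at an unadjusted p below 0.05), while 3 were lower adjusted over the list alone, and camera placed the list below other genes (median -2.38, adjusted p = 0.00359, adjusted p = 0.975 with an estimated correlation). CAB2R (LOC_Os01g41710), for a chlorophyll-binding protein, measured 46.9, 40.2 and 849 FPKM in WT replicates 1 to 3 and 13.7, 7.58 and 8.03 FPKM in ostie1-1 (log2 fold change -3.36, SE 1.09, adjusted p = 0.141). LHCA4 (LOC_Os08g33820) and CAB1R (LOC_Os09g17740) had log2 fold changes of -3.4 (SE 1.10, adjusted p = 0.138) and -3.35 (SE 1.16, adjusted p = 0.164). The high WT values lay in replicate 3, which exceeded both other WT libraries in 9 of 9 photosynthesis genes by a median log2 difference of 4.97. Without it the list median was -0.67 and the camera call was lost (adjusted p = 0.198), while 2 of 9 genes passed with limma, both lower in ostie1-1. These were LHCA4 (log2 fold change -1.73, adjusted p = 0.0226) and CAB2R (-1.71, adjusted p = 0.0283), and CAB1R had -1.65 (adjusted p = 0.0661).

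Other lists held single genes that passed at stage 10, here named after their values were seen except for those of the clock. MADS6 (LOC_Os02g45770), a floral organ identity gene active in lodicules, carpels and ovules, rose from 2.75 ± 1.01 to 97.8 ± 33.4 FPKM (n = 3 each, log2 fold change 4.82, SE 0.61, adjusted p = 0.00265). It was the 1 of 4 tested pistil and glume MADS genes that passed (median 0.28). MADS58 (LOC_Os05g11414), of the C class that specifies stamens, rose by 2.69 (SE 0.61, adjusted p = 0.0414), 1 of 4 stamen identity genes that passed (3 adjusted over the list alone). YUC5 (LOC_Os12g32750), for an auxin synthesis enzyme, rose from 1.04 ± 1.43 to 26.0 ± 22.1 FPKM (log2 fold change 3.69, SE 0.68, adjusted p = 0.0159) and was 1 of 11 auxin genes that passed (1 higher and 2 lower adjusted over the list alone). GA2ox3 (LOC_Os01g55240), for an enzyme that inactivates gibberellin, rose from 30.7 ± 6.51 to 143.0 ± 65.7 FPKM (log2 fold change 2.23, SE 0.41, adjusted p = 0.0170) and was 1 of 14 gibberellin genes (2 higher and 2 lower adjusted over the list alone). Of 4 clock genes, PRR1 (LOC_Os02g40510, log2 fold change 1.32, SE 0.24, adjusted p = 0.0167) and LUX (LOC_Os01g74020, 2.03, SE 0.38, adjusted p = 0.0177) rose. Both calls were lost with TPM, and that of PRR1 also with unscaled FPKM. Of 15 pollen wall and cuticle genes, WDA1 (LOC_Os10g33250), needed for anther wax, rose (log2 fold change 1.18, adjusted p = 0.0437), a call lost with each of the 3 other scalings, where 1 other member passed. The starch synthase gene SSIIc (LOC_Os10g30156) was the 1 of 16 starch genes that passed (log2 fold change -1.22, adjusted p = 0.0408), and the water channel gene PIP1;3 (LOC_Os02g57720) the 1 of 16 aquaporin genes (-1.98, adjusted p = 0.0186). The SSIIc call was lost with unscaled FPKM and with TPM.

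None of 10 tapetum, 5 sugar supply, 8 late pollen, 17 secondary wall, 11 meiosis, 10 heat shock, 4 respiratory burst oxidase and 3 reference genes passed in limma at stage 10, and 1 meiosis gene was higher adjusted over the list alone. At an unadjusted p below 0.05 they held 1, 1, 2, 2, 1, 2, 0 and 0 genes. Camera passed none of the other lists, and its adjusted p was 0.0856 for pollen wall and cuticle genes (median 0.79, 0.40 with quantile normalization) and 0.568 or more for the lists not yet described. Median, mean and camera differed in sign in several lists: tapetum (-0.03, 0.30, up), sugar supply (-0.06, 0.20, up), heat shock (-0.31, 0.07, up) and gibberellin genes (-0.16, 0.15, down). WT stage 10 replicate 3 exceeded both other WT libraries in 17 of 17 secondary wall genes (median 3.19), 10 of 10 heat shock genes (2.45), 15 of 16 aquaporin genes (2.73) and 12 of 15 pollen wall genes (2.21). Without it camera called pollen wall (adjusted p = 0.00583, 7 of 15 members higher) and secondary wall genes (adjusted p = 0.0245, 7 of 17 higher), both up and both lost with an estimated correlation (adjusted p = 0.378 and 0.601). Fry without that library called 10 lists at stage 10, among them pollen wall (adjusted p = 0.00485), primary wall (0.00354), auxin (0.0208), gibberellin (0.0341), aquaporin (0.0394) and tapetum genes (0.0494), all up. Pollen wall genes were also called by camera without ostie1-1 stage 10 replicate 1 (adjusted p = 0.0225).

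Over all 21279 genes, 618 passed at stage 10, 500 higher and 118 lower in ostie1-1, and 3996 had an unadjusted p below 0.05. The largest rises were those of LOC_Os01g10110, from 0.685 ± 0.267 to 130 ± 20.7 FPKM (n = 3 each, log2 fold change 6.44, SE 0.27, adjusted p = 1.5e-06), and LOC_Os01g04050 (6.07, SE 0.96, adjusted p = 0.00808). The largest falls were those of LOC_Os10g05750 (-8.88, SE 0.82, adjusted p = 5.1e-04), at 484, 577 and 3270 FPKM in WT and 2.28, 0.596 and 0.336 in ostie1-1, and LOC_Os10g05980 (-5.99, SE 0.87, adjusted p = 0.00570). These 4 genes and MADS6 passed whichever library was left out. The count rose to 7134 without WT stage 10 replicate 3 (3952 higher, 3182 lower), which included all 618. It dropped to 182 and 209 without WT stage 10 replicates 1 and 2, to 366, 157 and 343 without ostie1-1 stage 10 replicates 1, 2 and 3, and to 410, 393 and 385 without WT stage 12 replicates 1, 2 and 3. Of 17 named genes that passed, 12 were lost without WT stage 10 replicate 1 or ostie1-1 stage 10 replicate 2 and 10 without WT stage 10 replicate 2. Leaving out others cost fewer: 6 and 9 were lost without ostie1-1 stage 10 replicates 1 and 3, 4 without any one WT stage 12 library and 3 without either ostie1-1 stage 12 library. With only the 6 stage 10 libraries fitted, 111 genes passed and 14 of the 17 named genes were lost, all but LOC_Os01g10110, LOC_Os10g05750 and MADS6. Examples of calls lost with 1 library left out are JAZ8 at an adjusted p = 0.125 and the lipoxygenase gene at 0.131 without ostie1-1 stage 10 replicate 2. With unscaled FPKM or TPM the median log2 fold change of all genes shifted from -0.01 to -0.13 or -0.20 at stage 10 and from 0.05 to -0.21 or -0.30 at stage 12 (-0.11 with quantile normalization), and the rises reported here are relative to the median-of-ratios scale.

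At stage 12, 3 JA signalling genes and 2 JA-inducible defence genes rose in ostie1-1. JAZ10 (LOC_Os03g08330) rose from 4.89 ± 2.17 (n = 3) to 36.3 ± 18.4 FPKM (n = 2), a log2 fold change of 2.95 (SE 0.61, adjusted p = 0.0257). JAZ14 (LOC_Os10g25250) rose from 38.9 ± 13.5 to 117.0 ± 31.8 FPKM (1.94, SE 0.44, adjusted p = 0.0371) and JAZ8 from 4.06 ± 2.24 to 15.5 ± 2.84 FPKM (2.12, SE 0.50, adjusted p = 0.0420). JAmyb (LOC_Os11g45740), a JA-induced MYB gene, rose from 1.97 ± 1.35 to 20.3 ± 2.32 FPKM (3.17, SE 0.57, adjusted p = 0.0125), and CPS2 (LOC_Os02g36210), for a diterpene phytoalexin enzyme, rose by 1.77 (SE 0.35, adjusted p = 0.0214). In each of these genes both mutant libraries were above all 3 WT libraries.

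Of 14 JA signalling genes, 3 rose and 11 did not pass (4 adjusted over the list alone). The median was 0.83 (0.56 with unscaled FPKM, 0.52 with TPM) and camera adjusted p was 0.0234 (adjusted p = 0.816 with an estimated correlation). With unscaled FPKM, TPM or quantile normalization JAZ10 passed, and JAZ14 and JAZ8 did not. MYC2 had a log2 fold change of 1.55 (SE 0.50, adjusted p = 0.122). Of 10 JA-inducible defence genes, 2 rose and 8 did not pass (3 adjusted over the list alone), and the CPS2 call was lost with TPM. The median was 1.68 and camera adjusted p was 0.00972 (adjusted p = 0.816 with an estimated correlation). WRKY45 (LOC_Os05g25770) had a log2 fold change of 1.37 (SE 0.47, adjusted p = 0.148). Of 11 JA biosynthesis genes, the lipoxygenase gene LOC_Os04g37430 rose from 1.54 ± 0.688 to 14.0 ± 10.9 FPKM (2.62, SE 0.61, adjusted p = 0.0405), while 10 did not pass (1 adjusted over the list alone), and with TPM none did. Camera gave the list an adjusted p = 0.0567 (median 0.70, with 0.43 for unscaled FPKM and 0.41 for TPM). AOS1 had 12.5 ± 0.602 FPKM in WT and 45.1 ± 5.76 FPKM in ostie1-1 (log2 fold change 2.10, SE 0.73, adjusted p = 0.151). The fit shares its variance with stage 10, and without WT stage 10 replicate 3 the adjusted p of AOS1 was 0.00468. Then 4 of 11 JA biosynthesis, 5 of 14 JA signalling and 6 of 10 defence genes passed, all higher, with camera adjusted p of 0.0250, 0.0136 and 0.00347 (0.0103, 0.00168 and 0.0103 with fry, which called no list at stage 12 with all libraries). These camera calls were lost with an estimated correlation (adjusted p = 0.433, 0.344 and 0.433). Camera also called JA biosynthesis without WT stage 10 replicate 2 (adjusted p = 0.0480). Without ostie1-1 stage 12 replicate 1 the calls of JA signalling (adjusted p = 0.244) and defence genes (adjusted p = 0.150) were lost.

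**Figure D2:**
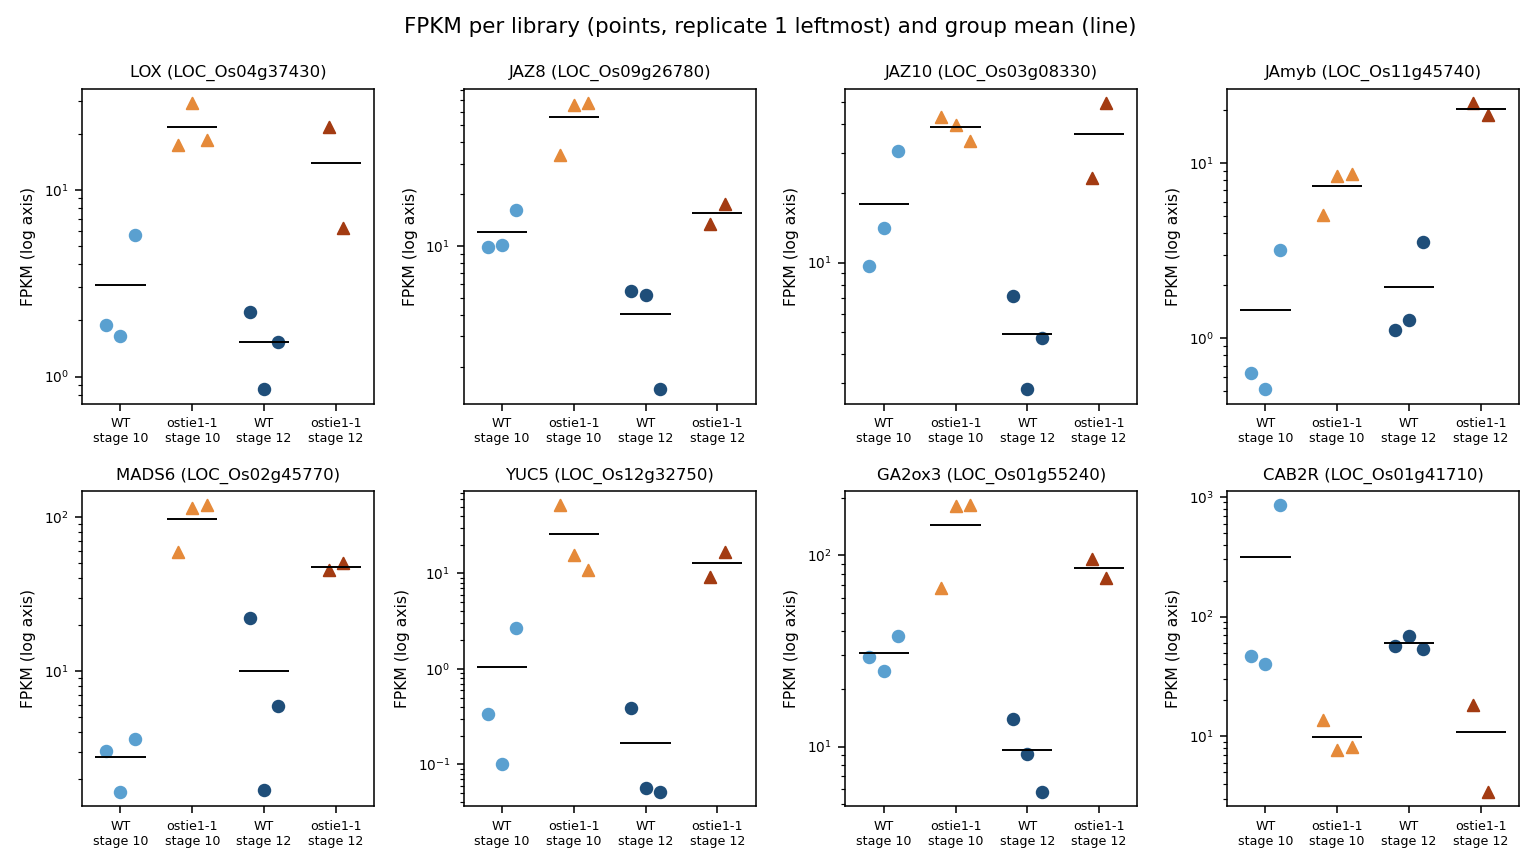
FPKM per library on a log axis for 8 genes, with groups along the horizontal axis, replicate 1 leftmost in each group, and the group mean as a line. JAZ8 and GA2ox3 lie higher in every ostie1-1 library than in the WT libraries of the same stage, and the CAB2R value of 849 FPKM is that of WT stage 10 replicate 3.

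Camera at the preset correlation placed heat shock genes higher and photosynthesis genes lower in ostie1-1 at stage 12. Of 10 heat shock genes, 0 passed with limma (6 at an unadjusted p below 0.05) and 5 were higher adjusted over the list alone. The median was 2.19 and camera adjusted p was 0.00601 (adjusted p = 0.816 with an estimated correlation). The small heat shock protein gene LOC_Os01g04370 had 0.511 ± 0.805 FPKM in WT (n = 3) and 5.54 ± 3.85 FPKM in ostie1-1 (n = 2), a log2 fold change of 2.28 (SE 0.63, adjusted p = 0.0786). The WT libraries differed in this list. LOC_Os04g01740, for an HSP90 chaperone, measured 33.7 FPKM in WT stage 12 replicate 1, 0.791 and 1.04 in replicates 2 and 3, and 32.1 and 36.1 in ostie1-1 (3.1, SE 1.09, adjusted p = 0.158). LOC_Os03g16030 measured 49.7, 2.36 and 2.07 in WT and 45.4 and 51.4 in ostie1-1 (2.93, SE 1.05, adjusted p = 0.162). Without WT stage 12 replicate 1 the camera adjusted p of the list was 3.6e-08. Of 9 photosynthesis genes, 0 passed with limma over all genes or adjusted over the list alone (1 at an unadjusted p below 0.05), and camera placed the list below other genes (median -1.82, adjusted p = 0.0194, adjusted p = 0.816 with an estimated correlation). CAB2R had 59.8 ± 7.85 FPKM in WT and 10.8 ± 10.4 in ostie1-1 (-2.39, SE 1.22, adjusted p = 0.302). The Rubisco small subunit gene LOC_Os12g19381 and LHCB4 (LOC_Os07g37240) had log2 fold changes of -2.43 (SE 1.00, adjusted p = 0.217) and -2.14 (SE 1.22, adjusted p = 0.352). Without WT stage 10 replicate 3, 5 of the 9 were lower in ostie1-1 (camera adjusted p = 2.5e-04, adjusted p = 0.433 with an estimated correlation), and without ostie1-1 stage 12 replicate 2 the call was lost (adjusted p = 0.0917).

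Other lists held single genes that passed at stage 12, named after their values were seen. GA2ox3 rose from 9.62 ± 4.08 (n = 3) to 85.9 ± 14.0 FPKM (n = 2, log2 fold change 3.43, SE 0.46, adjusted p = 0.00314) and passed whichever library was left out, 1 of 14 gibberellin genes to pass (1 higher and 1 lower adjusted over the list alone). The auxin gene YUC5 rose by 3.68 (SE 0.76, adjusted p = 0.0249), 1 of 11 auxin genes (3 higher and 1 lower adjusted over the list alone). MADS6 rose from 9.96 ± 10.8 to 47.6 ± 3.52 FPKM (3.00, SE 0.68, adjusted p = 0.0371), 1 of 4 pistil and glume genes. MADS3 (LOC_Os01g10504), a C-class stamen gene, rose by 1.65 (SE 0.34, adjusted p = 0.0252), 1 of 4 stamen identity genes (2 adjusted over the list alone). CESA5 (1.82, SE 0.42, adjusted p = 0.0380), the tonoplast water channel gene TIP2;1 (LOC_Os02g44080, 2.30, SE 0.53, adjusted p = 0.0391) and PRR1 (1.29, SE 0.27, adjusted p = 0.0275) each were the 1 member of their list to pass, of 5, 16 and 4. Calls of MADS6, MADS3, CESA5, TIP2;1 and PRR1 were lost with at least 1 other scaling. Calls in the opposite direction came up too: 1 aquaporin gene was lower with unscaled FPKM and TPM, and 1 gibberellin gene was lower with all 3 other scalings.

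None of 16 TCP, 10 tapetum, 15 pollen wall, 5 sugar supply, 16 starch, 8 late pollen, 17 secondary wall, 11 meiosis, 4 respiratory burst oxidase and 3 reference genes passed in limma at stage 12, with 2 pollen wall genes higher adjusted over the list alone. At an unadjusted p below 0.05 they held 2, 2, 3, 0, 3, 2, 3, 0, 0 and 1 genes. TCP21 (LOC_Os07g05720) had a log2 fold change of 2.23 (SE 0.69, adjusted p = 0.112), and the TCP list had a median of 0.20 (camera adjusted p = 0.435). Camera passed no other list, with an adjusted p of 0.120 for auxin genes (median 1.24) and 0.256 or more for the rest. Without ostie1-1 stage 12 replicate 1 starch genes were called lower (adjusted p = 0.0427), and without WT stage 10 replicate 3 fry called auxin genes higher (adjusted p = 0.0128). Median, mean and camera differed in sign for gibberellin genes (-0.28, 0.29, down) and sugar supply (-0.17, 0.03, down). Medians of tapetum (0.16) and secondary wall genes (0.26) turned to -0.10 and -0.14 with TPM, and that of primary wall genes (0.29) to -0.08. The medians of TCP (0.20) and reference genes (0.52) were 0.05 and 0.07 with TPM.

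Over all genes, 750 passed at stage 12, 685 higher and 65 lower in ostie1-1 (4191 at an unadjusted p below 0.05). The largest rises were those of LOC_Os06g49190, from 1.5 ± 0.122 (n = 3) to 164.0 ± 5.45 FPKM (n = 2, log2 fold change 6.30, SE 0.91, adjusted p = 0.00426), and LOC_Os09g22000 (5.32, SE 0.93, adjusted p = 0.0102). The largest falls were those of LOC_Os10g05750, at 71.7, 26.9 and 16.3 FPKM in WT and listed at 0 in both ostie1-1 libraries (adjusted p = 0.0167), and LOC_Os08g34984 (-4.37, SE 0.72, adjusted p = 0.00769). The count was 3501 without WT stage 10 replicate 3 (2331 higher, 1170 lower), which included all 750. It was 499 without ostie1-1 stage 10 replicate 2, 465, 293 and 398 without WT stage 12 replicates 1, 2 and 3, and 434 and 417 without ostie1-1 stage 12 replicates 1 and 2. Of 17 named genes that passed, 14 were lost without WT stage 12 replicate 2 or ostie1-1 stage 12 replicate 1 and 11 without ostie1-1 stage 12 replicate 2, as was JAZ10 at an adjusted p = 0.206. Without WT stage 12 replicates 1 or 3, 9 were lost, without ostie1-1 stage 10 replicates 1, 2 and 3, 2, 7 and 4, and without WT stage 10 replicates 1 and 2, 4 and 3. With only the 5 stage 12 libraries fitted, 1774 genes passed and 0 of the 17 were lost.

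**Figure D3:**
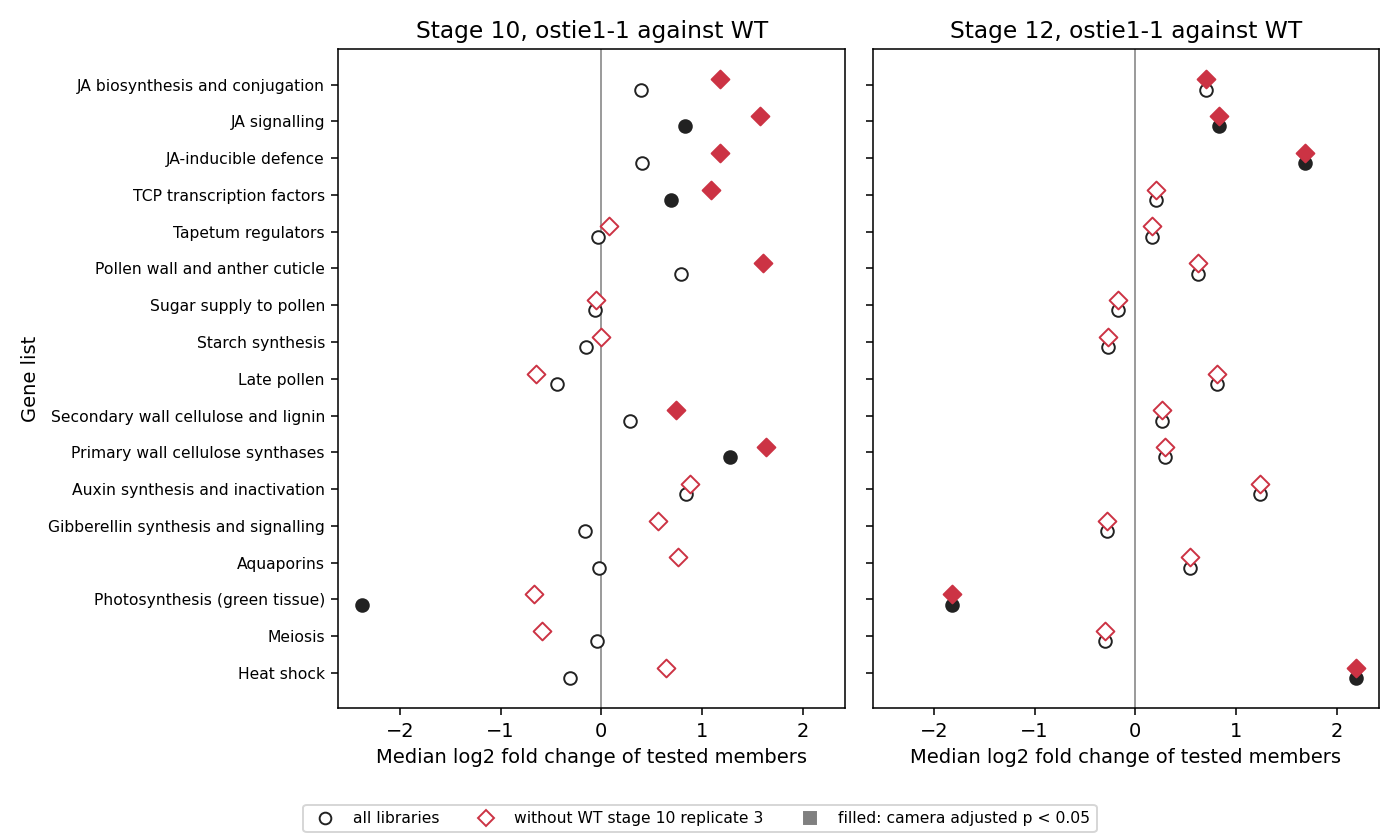
Median log2 fold change of the tested members of the 17 lists tested by camera, ostie1-1 against WT, at stage 10 (left) and stage 12 (right), with all libraries (circles) and without WT stage 10 replicate 3 (diamonds). Filled symbols have a camera adjusted p below 0.05 at the preset correlation, and the photosynthesis median at stage 10 moves from -2.38 to -0.67 without that library.

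The genotype effects at both stages were compared. Of the genes that passed, 190 did so at both stages in the same direction, 167 higher and 23 lower in ostie1-1. In opposite directions 0 passed, and independent lists would share 16.1 higher and 0.36 lower genes (Fisher's exact test for the higher genes, one-sided, p = 5.9e-126). Log2 fold changes at the stages correlated at 0.70 across genes, which are not independent replicates. The lipoxygenase gene LOC_Os04g37430, JAZ8, MADS6, YUC5, GA2ox3 and PRR1 were among the higher genes and LOC_Os10g05750 among the lower. Both comparisons share one variance estimate, and with separate fits 62 genes were shared. The count was 2314 without WT stage 10 replicate 3, 76 and 88 without replicates 1 and 2 of that group, 70 without ostie1-1 stage 10 replicate 2, 103, 73 and 86 without WT stage 12 replicates 1, 2 and 3, and 123 and 77 without ostie1-1 stage 12 replicates 1 and 2.

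The difference of the genotype effect between the stages was tested directly, and 4 of 21279 genes passed (1153 at an unadjusted p below 0.05), all with a larger rise at stage 12. All 4 lay at or near 0 in the other groups, so their SE draws on groups with little spread. With TPM, with a pseudocount of 0.1 or 0.01, with an FPKM of at least 5 and with a replicate block, 0 passed. The count was 7 without ostie1-1 stage 12 replicate 2, 1 without ostie1-1 stage 10 replicate 2 or WT stage 12 replicate 1 or 2, and 0 without WT stage 10 replicate 1 or 2, WT stage 12 replicate 3 or ostie1-1 stage 10 replicate 1 or 3. LOC_Os03g40800, chosen after its values were seen like the others, measured 24.2 and 20.9 FPKM in ostie1-1 at stage 12, up to 1.07 FPKM in WT at stage 12, and was listed at 0 in all WT stage 10 libraries (log2 difference 4.01, SE 0.40, adjusted p = 0.0134). Among the lists, camera called heat shock (median difference 2.36, adjusted p = 7.1e-04) and JA-inducible defence genes (1.25, adjusted p = 0.0192), both with a larger effect at stage 12 and both at an adjusted p = 0.883 with an estimated correlation. Without WT stage 10 replicate 3 both calls were lost (adjusted p = 0.0995 and 0.452), 18 genes passed, and TCP genes were called with a smaller difference at stage 12 (median difference -0.65, adjusted p = 0.00220). Primary wall (-1.13, adjusted p = 0.0155) and pollen wall genes (-0.62, adjusted p = 0.0250) also had a smaller difference at stage 12. Photosynthesis genes were further below WT at stage 12 (-0.99, adjusted p = 0.0201), and late pollen genes were shifted upward (1.43, adjusted p = 0.0250). All 5 lists were lost with an estimated correlation (adjusted p = 0.530 to 0.677).

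From stage 10 to stage 12 in WT, 4 late pollen genes rose. The profilin gene LOC_Os10g17660, for an actin-binding protein of pollen, rose from 74.3 ± 52.5 to 699.0 ± 232.0 FPKM (n = 3 each, log2 fold change 3.16, SE 0.48, adjusted p = 0.0125). EXPB1 (LOC_Os03g01610), for a pollen beta-expansin, was listed at 0 in 2 of 3 WT libraries at stage 10 and measured 78.3, 19.5 and 233 FPKM at stage 12 (adjusted p = 0.0131). Of 8 late pollen genes, 4 rose and 4 did not pass (7 adjusted over the list alone), with a median of 3.03 and a camera adjusted p of 2.2e-09 (adjusted p = 0.260 with an estimated correlation). Among 14 JA signalling genes, JAZ14 rose by 1.97 (SE 0.39, adjusted p = 0.0282) and JAZ11 fell by 2.47 (SE 0.48, adjusted p = 0.0269), with 2 higher, 1 lower and 11 not passing (3 and 3 adjusted over the list alone). Camera placed secondary wall (median -1.52, adjusted p = 4.9e-05), pollen wall (-1.51, adjusted p = 4.7e-04) and tapetum genes (-0.90, adjusted p = 0.0115) lower at stage 12 and starch genes higher (0.43, adjusted p = 0.0387), all lost with an estimated correlation (adjusted p = 0.812, and 0.630 for the others). Of their 17, 15, 10 and 16 members, 1 pollen wall gene fell and the rest did not pass (7, 5 and 3 secondary wall, tapetum and starch genes at an unadjusted p below 0.05).

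Over all genes 558 passed between the stages in WT, 449 higher and 109 lower at stage 12 (2995 at an unadjusted p below 0.05). The count was 35 without WT stage 10 replicate 2, 293, 271 and 9 without WT stage 12 replicates 1, 2 and 3, and 330 without ostie1-1 stage 10 replicate 2. It was 520 without WT stage 10 replicate 3, 407 of them shared. The tapetum call was lost without WT stage 12 replicate 3 (adjusted p = 0.0686), as was the starch call without WT stage 10 replicates 1 or 2 or WT stage 12 replicates 2 or 3 (adjusted p = 0.0553 to 0.0976). JAZ11, JAZ14, the profilin gene and EXPB1 were all lost without WT stage 12 replicate 3 (adjusted p = 0.146, 0.152, 0.0859 and 0.0647) and without WT stage 10 replicate 2. Without WT stage 10 replicate 3 the medians shrank to -0.56 in secondary wall (adjusted p = 0.0457), -0.33 in pollen wall (adjusted p = 0.0433) and -0.52 in tapetum genes (adjusted p = 0.0433). Those of starch (0.39, adjusted p = 0.0433) and late pollen genes (3.04, adjusted p = 2.1e-07) moved less. Photosynthesis genes, with a median of -0.54 before, were then called higher at stage 12 (1.02, adjusted p = 0.00479), as were aquaporin (0.62, adjusted p = 0.00676) and JA-inducible defence genes (0.61, adjusted p = 0.0433). These 8 lists had an adjusted p of 0.373 to 0.579 with an estimated correlation. JA biosynthesis genes were called lower at stage 12 without WT stage 10 replicate 1 or 2 (adjusted p = 0.0220 and 0.0102), and photosynthesis and TCP genes without replicate 2 (adjusted p = 0.0279 and 0.0336). Heat shock genes, at a camera adjusted p = 0.930 with all libraries, were called lower at stage 12 without WT stage 12 replicate 1 (adjusted p = 0.00878).

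The stage change in ostie1-1 was compared with that in WT over the 558 genes, which were selected for their change in WT. It had a slope of 0.99 on that in WT (0.84 to 1.13 with 1 library left out), 98.6% of the genes had the same sign, and 474 passed in both genotypes in the same direction. The genes that rose in WT had a median genotype difference of 0.30 at stage 10 and 1.00 at stage 12. In ostie1-1, 6 of 8 late pollen genes rose (8 adjusted over the list alone, median 3.29, camera adjusted p = 6.2e-07, adjusted p = 0.499 with an estimated correlation). Fry called late pollen genes in WT (adjusted p = 0.0216) and in ostie1-1 (adjusted p = 0.00672). Without WT stage 10 replicate 3 the WT call of fry was lost (adjusted p = 0.107) and that in ostie1-1 was kept (adjusted p = 0.00828). Camera also called pollen wall and primary wall genes (both adjusted p = 0.0146), TCP genes (adjusted p = 0.0182) and secondary wall genes (adjusted p = 0.0453) lower and heat shock genes higher (adjusted p = 0.0162) at stage 12, with adjusted p of 0.7 to 0.731 with an estimated correlation. Without WT stage 10 replicate 3 tapetum genes were called lower as well (adjusted p = 0.0460, adjusted p = 0.512 with an estimated correlation). Over all genes 2282 passed in ostie1-1, 1655 higher and 627 lower (5252 at an unadjusted p below 0.05). This count was 4795 without WT stage 10 replicate 3, 1238 and 1517 without ostie1-1 stage 10 replicates 2 and 3, and 818 without ostie1-1 stage 12 replicate 1. The stage index, from the genes selected in WT, was -2.21 ± 0.61 in ostie1-1 and -2.64 ± 0.73 in WT at stage 10 (SD, n = 3 each, exact two-sided permutation p = 0.5) and 3.4 ± 0.72 (n = 2) and 2.75 ± 0.82 (n = 3) at stage 12 (exact p = 0.400). Neither difference exceeded the spread between libraries, and neither test could reach a p below 0.1.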

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

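The tests on WT stage 10 replicate 3 for a wrong label and for green tissue, and the test of MADS6 for green tissue, were chosen after the results were seen, while those for younger anthers, for a chromosome block and for other splits of the libraries were written first. The bounds of 2 tests were also changed after their values were seen. For genes with a large genotype difference, a stricter bound tried first, a majority on the wild-type side with ostie1-1 libraries under 25%, was not met at 41.3%, which left that test undecided, and the bound of the test on all genes that separate the genotypes was then used in its place. For photosynthesis genes, MADS genes of other organs were asked to be higher too, which turned a test that had been in favour of green tissue into an undecided one.

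The effect of ostie1-1 differed between the stages in 4 genes, by the test of that difference over all 21279 genes, and in 0 with TPM, with a pseudocount of 0.1 or 0.01, with an FPKM of at least 5 or with a replicate block. LOC_Os03g40800 had a log2 difference of 4.01 (SE 0.40, adjusted p = 0.0134), with 24.2 and 20.9 FPKM in ostie1-1 at stage 12. The difference was 2.32 for LOC_Os04g17220, at 4.93 and 2.69 FPKM in ostie1-1 at stage 12 and listed at 0 in all other libraries. It was 2.32 for LOC_Os08g33170 (4.80 and 3.35 FPKM) and 2.34 for LOC_Os06g13780 (5.51 and 2.98 FPKM), both at most 0.334 FPKM elsewhere. The adjusted p of these 3 genes was 0.0353. Depth limits what their low values show, and only the 2 ostie1-1 stage 12 libraries brought them past the filter on low values. For all 4 genes the variance is shared with groups at or near 0, which have little spread. The SE and adjusted p therefore say little about the spread between those 2 libraries. Without 1 library the number of genes lay between 0 and 18, as given above by library, with 18 without WT stage 10 replicate 3.

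WT stage 10 replicate 3 resembled the ostie1-1 libraries of its stage in most of the 2314 genes that separate the genotypes at both stages without it. On the wild-type side lay 18.9% of them, and 41.3% of the 75 genes with a log2 difference of at least 3. Each other stage 10 library was scored on its own set of genes (1076 to 2712, and 67 to 88 with the large difference). The shares were 1.84% to 9.32% in left-out ostie1-1 libraries and 99% and 99.5% in WT replicates 1 and 2. With the large difference they were 0% to 5.68% in ostie1-1 and 100% in both WT libraries. Between WT at 0 and ostie1-1 at 1 the median position of WT stage 10 replicate 3 was 0.98 and 0.57. Left-out ostie1-1 libraries lay at 0.79 to 1.12 and 0.78 to 1.11, so only the genes with a large difference set it below their range. Its shares, above those of ostie1-1 and far below those of WT, argue against a mislabelled library like the other ostie1-1 ones but do not make it like WT. They come from unlike sets of genes. Carry-over of green floral tissue stays open for photosynthesis genes, which were higher than in the other WT stage 10 libraries by a median log2 difference of 4.97 while MADS genes of other organs differed by 0.62, but pollen wall and cuticle genes, which green tissue does not bring, were higher by 2.21 (bootstrap SE 0.70). Younger anthers are a candidate explanation, since the index from genes that change with stage in ostie1-1 was -1.88, against -0.11 and -0.58 in the other WT stage 10 libraries and -2.02 to -1.67 in ostie1-1. A likeness to ostie1-1 from any source would give that value. On the index from genes selected in WT, WT stage 10 replicate 3 lay at -3.02, between replicate 1 (-1.8) and replicate 2 (-3.11). That index thus did not set it below both, though the library was itself used to select those genes. Gene lists tied to a phase of anther development went both ways. Against the other 2 WT stage 10 libraries, tapetum genes were higher (median log2 difference 0.87) and late pollen genes lower (-0.68). Genes of meiosis, an earlier step, were not raised as a set (-1.22), with 7 of 11 below both libraries and 4 above. A difference in the day or plants of sampling was not tested, since the labels give none.

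MADS6 was higher in ostie1-1 at both stages (log2 fold change 4.82 and 3.00), and the gene is also active in other floral organs. Green lemma or palea tissue in the ostie1-1 samples would raise photosynthesis genes. Their median was -2.38 at stage 10, or -0.67 without WT stage 10 replicate 3. At stage 12, where that library does not enter the fold change, it was -1.82. The negative medians argue against green tissue, though they were known when the test was chosen. Carry-over of lodicule or pistil tissue stays open, since most MADS genes of those organs were not tested and the other 3 tested members of that list did not pass at either stage. A biological effect of the mutation on MADS6 stays open as well and was not tested further.

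The 190 genes changed at both stages may include some from a chromosome block from another background that ostie1-1 carries beside the mutation. The densest window of 100 consecutive tested loci held 6 of them, between LOC_Os01g09370 and LOC_Os01g11470, where random draws had a median of 5 (permutation p = 0.238, 10000 draws). By its locus number LOC_Os01g10110, the gene with the largest rise at stage 10, lies within that window. The genes with the largest falls at stage 10, LOC_Os10g05750 and LOC_Os10g05980, also have nearby locus numbers. Whether a block holds any of them was not tested. A block with a few of these genes cannot be told apart from none, since 6 genes are close to what random draws give.

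For the 618 genes at stage 10 the 6 libraries allow 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many genes, with 0 as the highest of the others. The 558 genes between the stages in WT also had 10 splits, too few for a share under 0.05, with 1 split giving as many and 1 gene as the highest of the others.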

How the results depend on the processing

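Restricting the analysis to loci with 1 transcript model was chosen after seeing the data, and all other alternatives before. With it no count of genes or lists moved by more than 1.5 times. Of 78 named results, the 42 past the threshold kept their direction under every alternative that gave them a value, which 36 had with an FPKM of at least 5, 40 with 1 transcript model and 38 with only the groups of the comparison. Values that did not pass could change sign, as that of JAR2 (LOC_Os01g12160), a JA conjugation gene, at stage 10 (log2 fold change -1.51, SE 1.10, adjusted p = 0.472, and 0.09 without WT stage 10 replicate 3). Calls were lost in 11 with unscaled FPKM, 18 with TPM, 7 with quantile normalization, 14 and 25 with the pseudocounts of 0.1 and 0.01, and 14 with no filter. With only the groups of the comparison 16 were lost and 7 gained, 4 were lost with an FPKM of at least 5, and 1 was lost and 22 were gained with array weights.

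The causes of the moved values below were not tested, except where fewer libraries or genes by construction changed the variance estimate. At stage 10, 280 genes passed with a pseudocount of 0.01 and robust variances, 111 with only the groups of the comparison, and 10803 with array weights, against 618. At stage 12, against 750, 499 passed with TPM, 284 and 98 with the pseudocounts of 0.1 and 0.01, 1166 with no filter, 331 with an FPKM of at least 5, 1774 with only the groups of the comparison and 1607 with array weights. Between the stages in WT, against 558, 351 passed with the pseudocount of 0.01, 62 with no filter, 319 with only the groups of the comparison and 2774 with array weights. In ostie1-1 1155 passed with the pseudocount of 0.01, against 2282. At both stages, against 190, 51 passed with the pseudocount of 0.01, 125 with no filter, 122 with an FPKM of at least 5, 62 with separate fits and 1195 with array weights. The iteration for array weights did not converge fully.

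For the difference between the stages, against 4 genes, 7 passed with unscaled FPKM, 8 with quantile normalization, 193 with no filter and 49 with array weights. With limma on TPM, with either lower pseudocount and with an FPKM of at least 5, 0 passed (1153 at an unadjusted p below 0.05 with all choices as reported). The slope of the stage change in ostie1-1 on that in WT was 0.76 with the pseudocount of 0.01, against 0.99.

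Of the lists, 4 were called at each stage. Of these 4, 2 at stage 10 and 3 at stage 12 had a mean log2 fold change of at least 1 in size. At stage 10, 8 were called with no filter. At stage 12, 0 were called with no filter. With an estimated correlation and with fry 0 lists were called at either stage with all libraries. Without WT stage 10 replicate 3 fry called 10 lists at stage 10 and 4 at stage 12, and camera with an estimated correlation 0 at either.

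Replicate numbers did not pair the libraries: deviations from the group means of libraries with the same number correlated at -0.28 to 0.12. With a replicate block 331 genes passed at stage 10, 106 at both stages and 0 for the difference between the stages, and 18 of the named calls were lost.

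Leaving out 1 library at a time gave 157 to 7134 genes at stage 10, 293 to 3501 at stage 12, 9 to 576 between the stages in WT, 818 to 4795 in ostie1-1, 0 to 18 for the difference and 70 to 2314 at both stages. The lists called ranged from 3 to 7 at stage 10 and from 3 to 5 at stage 12, and the slope from 0.84 to 1.13. The highest gene counts came without WT stage 10 replicate 3, except for the 576 genes in WT. Where 1 library of ostie1-1 at stage 12 was left, it was assumed to vary like the other groups. Depth limits genes at low FPKM.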

Other observations

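The values in this part were examined after the results were seen and no explanation was tested for them. The genes that rose from stage 10 to stage 12 in WT (449) had a median genotype difference, ostie1-1 against WT, of 0.30 at stage 10 and 1.00 at stage 12 on the log2 scale, and those that fell (109) one of -0.11 and 0.09. These genes were selected on the WT libraries. For the genes that rose, this by itself would raise the difference at stage 10 and lower it at stage 12. The profilin genes LOC_Os10g17660 and LOC_Os10g17680 were among those that rose in WT. The former measured 1710 and 1050 FPKM in ostie1-1 at stage 12, against 541, 592 and 965 FPKM in WT, and the latter 1290 and 1170 FPKM against 369, 385 and 875 FPKM. Neither passed for the genotype at stage 12 in limma (adjusted p = 0.202 and 0.237). EXPB1, of the same list and also among those that rose in WT, had the lower mean in ostie1-1. It measured 23.6 and 7.9 FPKM there at stage 12, against 78.3, 19.5 and 233 FPKM in WT, and did not pass either.

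Several floral organ identity genes had values too low to test. MADS16 (LOC_Os06g49840), a B-class gene that specifies stamens, reached at most 0.0303 FPKM in any library and MADS2 (LOC_Os01g66030) 0.0483 FPKM, while the stamen gene MADS3 (LOC_Os01g10504) stood at 30.2 to 178 FPKM. MADS16 and MADS2 have 2 transcript models each in the table. Their values are therefore not read as a lack of B-class transcripts in these anthers.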
